A study of Mus musculus with 18 samples.

How the data were processed

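RNA sequencing of polyadenylated RNA from mouse colon was deposited for 18 libraries in 3 groups of 6, named vector, TNBS and IBC. Per the labels, total RNA was quality-checked on a chip-based electrophoresis system and polyadenylated RNA was selected on oligo(dT) beads, and the reads were trimmed with cutadapt 1.9. The aligner, the counting program, the annotation and the genome build are not given in the sources used here. The deposited table holds 35405 mouse genes with Ensembl identifiers, and per the file headers it gives a count and an FPKM value (fragments per kilobase of transcript and per 1e6 fragments) for every gene and library. The table names the vector libraries as control. All value columns were used.

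The deposited count columns were checked and hold whole numbers with a different total in each library, and the FPKM columns are proportional to them within each gene. Among low counts, 19961 gene and library pairs had a count of 4, against 9977 with 3 and 6358 with 5. Another 8462 pairs had a count of 8, against 5918 with 7. A sequenced fragment can therefore be worth more than 1 count, and a repeat with counts divided by 4 was added for this reason. Of 32979 genes shared with the GRCm38 GENCODE M21 annotation, 639 had the same start and end, so positions are printed as in the table without a build. Copies of mitochondrial genes on chromosome 1 (Atp6-ps, Gm28661, Gm28437) each held about as many counts as the mitochondrial gene they resemble (median ratios 1.04, 0.989 and 0.996).

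Genes with low counts were removed with filterByExpr of edgeR 4.0.16, which left 20855 genes, and totals were scaled by TMM. Genes were tested with edgeR's quasi-likelihood test in a single fit of all 18 libraries with a mean per group, and p-values were adjusted by Benjamini-Hochberg over the genes of each comparison at a threshold of 0.05. All tests were two-sided. Levels are counts per 1e6 counts of the scaled totals (CPM), given as mean ± SD with n = 6, and fold changes are log2 with their standard error. Other tools were limma 3.58.1, DESeq2 1.42.0 and the data.table package (version 1.17.8) under R 4.3.3. The total of each library sets the precision of its values. No upper limit is given where a gene had a count of 0, since the number of counts per fragment is not known.

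A set of 31 gene lists with 454 genes was fixed before the data were examined, as were the groups, the 3 comparisons, the tests, the rule for named genes and the other settings to be tried. The lists cover inflammatory and signalling pathways, cell types of the colon wall and tissues that could be carried over with it, and 427 of their genes were measured. Lists were tested with camera (limma) at a preset correlation of 0.01 between genes on log2 CPM with a prior count of 2, adjusted over the 31 lists of a comparison. Each list was also tested with camera at an estimated correlation and with fry, which asks whether its genes move on balance one way. The score of a list in a library is the mean of its centred log2 CPM. Differences between group means of scores were tested by exact permutation of the 924 assignments, adjusted over the 93 tests of 31 lists and 3 comparisons. Their 95% intervals come from the same permutations. Differences within the 12 libraries high in Hoxb13 or the other 6 are those of scores from all 18 libraries scaled together, unless a fit of the set alone is named, which filters and scales its libraries anew.

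The named-gene rule takes 10 fixed genes whatever their result (1 of them is not reported here), the 8 largest rises and 8 largest falls among called genes with enough expression and little overlap between groups, and up to 4 members of each list with the smallest p. Genes that fall outside this rule are said to be chosen after their values were seen. Fold changes of TNBS against vector were set against those of IBC against TNBS across genes. Because both share the TNBS libraries, the correlation was compared with 100 simulations of unchanged groups and with 20 assignments of the TNBS libraries to the contrasts with no TNBS library used for both.

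The methods were tested on simulated data made from the libraries. At a 4-fold change the gene test recovered 74%, 82% and 72% of changed genes in the comparisons of TNBS with vector, IBC with TNBS and IBC with vector. Between 1.95% and 5.30% of its calls were false. The simulated counts were drawn gene by gene, without structure shared by the genes of a library. Libraries were checked for duplicates, of which none were found, and for pairing by replicate number. Only 7 of 18 same-numbered pairs correlated above 0.1 (median -0.0208), so the libraries were treated as unpaired and the replicate number entered as a block only in an alternative.

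Other settings fixed in advance were other pseudocounts on FPKM, limma on log2 FPKM, no filter or a stricter filter on low counts, DESeq2 size factors, quantile normalization, library weights, the 2 compared groups alone, a replicate block, DESeq2 and leaving out each library in turn. Chosen after the data were seen were a score of Hox genes (Hoxb13 and Hoxd13 against Hoxb6 and Hoxb8) as a covariate, 12 libraries high in Hoxb13 alone, the other 6 alone, both also with an estimated correlation for lists, fits without TNBS replicate 5, and counts divided by 4. A test of 330 KEGG pathways from the table's annotation and lists of heat shock and immediate-early genes were also added then. Reads were not analysed here, so splicing and sequence variants are not reported.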

Results

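Gene expression was measured by RNA sequencing in 18 libraries of mouse colon. They form 3 groups of 6, named vector (the controls), TNBS (trinitrobenzene sulfonic acid, a hapten used to induce colitis) and IBC (isobavachalcone, a plant chalcone). The series title concerns isobavachalcone in TNBS colitis and GPR84, a receptor of myeloid cells for medium-chain fatty acids, with the kinases PI3K and AKT. The labels do not say whether the IBC animals also received TNBS, nor give doses or times. They do not say whether the libraries come from separate animals either, so the p-values measure the spread between libraries. Totals ran from 55.7 to 78.9 in units of 1e6 counts, with means of 65.4 ± 8.51 in vector, 65.2 ± 3.55 in TNBS and 67.3 ± 5.74 in IBC (SD, n = 6 each).

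The largest difference between libraries did not follow the groups. The first principal component held 25.8% of the variance and set apart 6 libraries, namely vector 3 and 4, TNBS 2 and 3, and IBC 2 and 5. Hoxb13, a homeobox gene of the hindmost body axis, was at most 1.44 CPM in these 6 and between 123 and 598 CPM in the other 12. Hoxb6, which marks more anterior positions, was 15.7 to 98.3 CPM in the 6 and 1.30 to 2.84 CPM in the 12. Each group holds 4 libraries high and 2 low in Hoxb13. For the called lists, differences within both sets are given beside the pooled ones, while values of single genes are pooled unless stated otherwise. Mitochondrial genes took 17.98% of the counts in vector 3, against 5.55% to 7.08% in the other vector libraries.

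**Figure D1:**
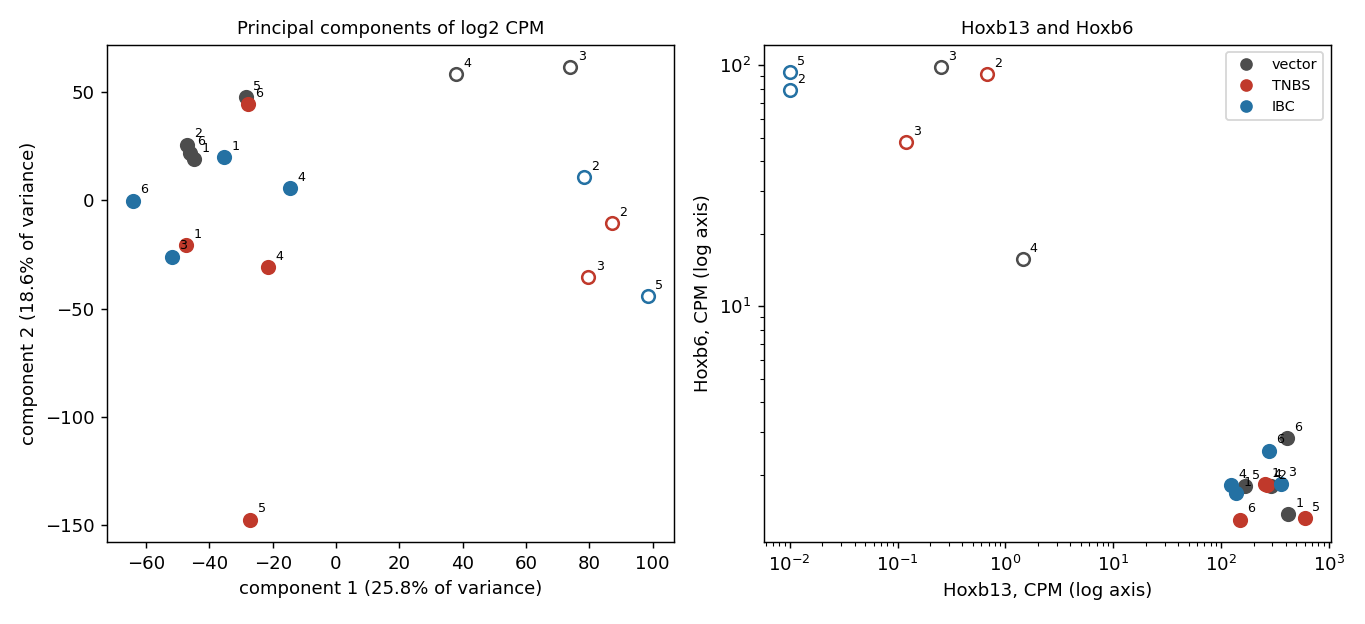
The left panel plots the first against the second principal component of log2 CPM for the 18 libraries, with replicate numbers. The right panel plots Hoxb13 against Hoxb6 in CPM on log axes, where 6 libraries reach at most 1.44 CPM of Hoxb13 and the other 12 at least 123 CPM.

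The comparison of TNBS with vector asks what the colitis model does to the tissue. Neutrophil markers and inflammatory cytokines and chemokines rose, and the score of each list was higher in all 6 TNBS libraries than in any vector library. The neutrophil score rose by 2.66 on the log2 scale (95% interval 1.37 to 4.12) and that of the cytokines by 2.26 (1.28 to 3.21). Mmp8, a neutrophil collagenase, went from 0.0402 ± 0.0723 to 2.03 ± 1.99 CPM, and S100a9, a subunit of calprotectin, from 0.436 ± 0.356 to 23.4 ± 46.7 CPM (SD, n = 6 each), of which TNBS 5 had 118 and the other TNBS libraries 0.838 to 12.03. Ccl2, which attracts monocytes, went from 1.03 ± 0.376 to 8.38 ± 7.29 CPM, and Cxcl1, which attracts neutrophils, from 0.337 ± 0.114 to 3.30 ± 2.61 CPM. Adjusted over the list alone, 16 of 18 neutrophil genes and 14 of 19 cytokine genes rose, against 0 in each list over all genes tested. Each score had an exact permutation p of 0.00216, the smallest that 924 assignments can give, and an adjusted p of 0.0403 over 93 tests. With an estimated correlation neither list passed camera (adjusted p = 0.191 for neutrophil markers and adjusted p = 0.143 for cytokines with an estimated correlation). The neutrophil difference was 2.595 in the 12 libraries high in Hoxb13 and 2.80 in the other 6, and that of the cytokines 1.94 and 2.89.

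**Figure D2:**
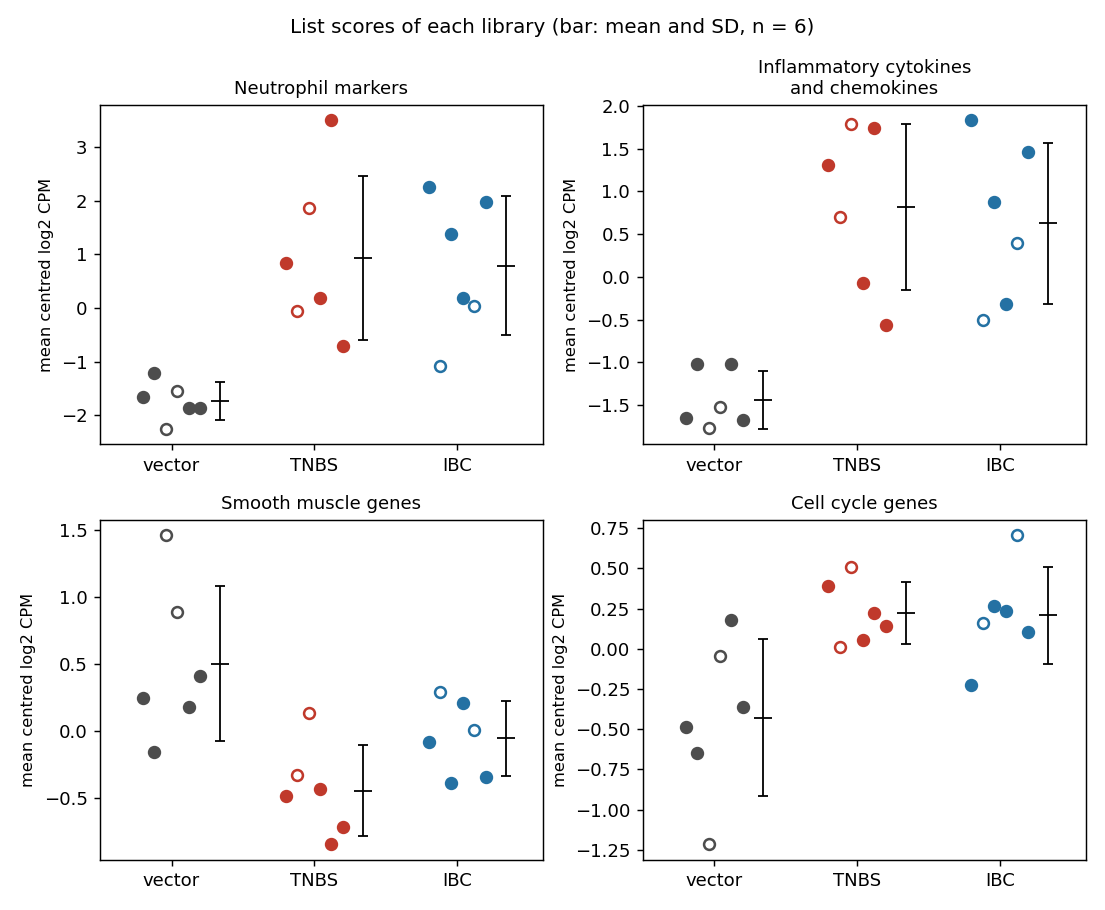
Scores of 4 gene lists (mean centred log2 CPM of the members) are plotted for each library by group, with the mean ± SD of n = 6 as bars and open symbols for the 6 libraries low in Hoxb13. The lowest TNBS neutrophil score of -0.71 lies above the highest vector score of -1.21.

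Camera at the preset correlation called 10 of 31 lists between TNBS and vector, 8 up and 2 down, and fry called 7. No list was called at the estimated correlation, and for the 8 lists other than neutrophils and cytokines the adjusted p = 0.247 (cell cycle, mast cell, smooth muscle and red blood cell), adjusted p = 0.191 (antimicrobial), adjusted p = 0.543 (monocyte and macrophage), adjusted p = 0.716 (extracellular matrix) and adjusted p = 0.524 (NF-kB) with an estimated correlation. None of these 8 passed the exact permutation test after adjustment (0.0671 to 0.192). Cell cycle genes were higher, with 15 of 20 rising when adjusted over the list alone (0 over all genes). Among them Cdk1, the kinase that starts mitosis, went from 32.1 ± 8.75 to 62.5 ± 21.3 CPM (SD, n = 6 each). In the list of antimicrobial and injured epithelium genes 7 of 16 rose over the list alone and 0 over all genes. Its member Lcn2, an iron-scavenging lipocalin, went from 2.23 ± 0.803 to 14.1 ± 17.5 CPM. Monocyte and macrophage markers rose in 9 of 20 genes, extracellular matrix genes in 5 of 20 and mast cell markers in 3 of 8 when adjusted over the list alone, against 0 over all genes. Smooth muscle markers fell in 6 of 12 genes over the list alone and 1 over all genes, and all 12 were lower. Myh11, the smooth muscle myosin heavy chain, went from 971 ± 678 to 297 ± 122 CPM. Red blood cell markers fell in 5 of 6 genes over the list alone and in 0 over all genes.

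The mean differences of these lists, in log2, were 0.65 for cell cycle, 1.56 for antimicrobial genes, 0.78 for monocytes and macrophages, 0.74 for extracellular matrix and 1.32 for mast cells. They were -0.95 for smooth muscle and -1.48 for red blood cells, and the NF-kB and Toll-like receptor list was called at 0.20 with 0 of 19 members passing over the list alone or over all genes. The NF-kB call was lost without vector 1 (0.17), vector 3 (0.20), vector 5 (0.19), TNBS 1 (0.21), TNBS 3 (0.12) or TNBS 6 (0.21). The extracellular matrix call was lost without TNBS 1 (0.55) or TNBS 4 (0.59).

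Within the 12 libraries high in Hoxb13 and then the other 6, the differences were 0.53 and 0.89 for cell cycle, 1.57 and 1.55 for antimicrobial genes, 0.70 and 0.93 for monocytes and macrophages, and 1.27 and 1.41 for mast cells. They were -0.79 and -1.27 for smooth muscle, -1.49 and -1.45 for red blood cells, 0.14 and 0.33 for the NF-kB list, and 1.03 and 0.15 for extracellular matrix. In the 12, the smallest exact p is 0.0286 (n = 4 per group), which neutrophil, cytokine, antimicrobial and smooth muscle scores reached, and in the 6, with 2 libraries per group, no exact p can reach 0.05. Among the 21 lists not called, mean differences ran from -1.77 for pancreatic acinar markers (3 of 10 measured, with a score of 8.49 in vector 6 and at most 0.44 in the other vector libraries) to 0.75 for squamous epithelium. The mean and the median differed in sign for B and plasma cells (0.00 and -0.21), eosinophils (0.28 and -0.03), crypt stem cells (-0.05 and 0.12) and fibroblasts (0.01 and -0.03).

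At the level of single genes, 4 genes passed over all 20855 tested. Chil3 (ENSMUSG00000040809), a chitinase-like protein of activated macrophages on chromosome 3 from 106054870 to 106074880, rose from 0.0104 ± 0.0256 to 17.3 ± 25.6 CPM (SD, n = 6 each, edgeR adjusted p = 0.0471), with 65.7 CPM in TNBS 5. Its log2 difference ran from 9.31 to 13.16 without 1 library, so no single fold is given. It was higher in 6 of 6 TNBS libraries than the vector median, its vector counts were 4 in vector 1 and 0 in the other 5, and the similar gene Chil4 can share its reads. Synm (ENSMUSG00000030554), the intermediate filament protein synemin of muscle on chromosome 7 from 67379908 to 67409441, fell by 1.72 ± 0.28 (log2, SE) from 122 ± 44.1 to 37.2 ± 14.1 CPM (edgeR adjusted p = 0.0471), with 6 of 6 TNBS libraries lower. The other 2 genes fall outside the rule for named genes and were chosen after their values were seen. Opcml (ENSMUSG00000062257), a cell adhesion molecule on chromosome 9 from 27702071 to 28836706, fell by 3.18 ± 0.46 from 0.903 ± 0.544 to 0.0983 ± 0.0281 CPM (edgeR adjusted p = 0.0316), lower in 6 of 6. Disp3 (ENSMUSG00000041544), on chromosome 4 from 148324721 to 148372422, had 8 to 16 counts in the vector libraries and 0 in all 6 TNBS libraries (edgeR adjusted p = 0.0484). No fold is given for it, since a fragment can be worth more than 1 count.

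The edgeR count of 4 stands beside 3703 genes at an unadjusted p under 0.05, of which 2177 were higher and 1526 lower. Uniform p-values would give 1043, and other splits of the same libraries into groups of 6 gave a median of 1036 and up to 4368. Groups did not overlap for 245 genes (1.17%, against 0.216% expected for a random split). The spread of that share over splits was not computed. DESeq2 called 574 genes (331 up and 243 down, 271 without TNBS 5) and limma on log2 FPKM called 0. With the Hox score as a covariate edgeR called 170 genes, and 10 without TNBS 5, while the 12 libraries high in Hoxb13 alone and the other 6 alone gave 0 each. Leaving out TNBS 6 gave 323 genes, 201 up and 122 down. The count was 0 without vector 1, vector 3, vector 6, TNBS 2, TNBS 3, TNBS 4 or TNBS 5, it was 1 without vector 5 or TNBS 1, and it was 2 without vector 2 or vector 4. Across the alternatives Chil3 was called in 8 of 29, Synm in 9 of 29, Opcml in 10 of 24 and Disp3 in 5 of 23.

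The genes named in the title were read in all groups. Gpr84 was at 0.0277 ± 0.0444 CPM in vector, 0.441 ± 0.547 in TNBS and 0.215 ± 0.137 in IBC (SD, n = 6 each). Its counts were 0 in vector 1, 2, 3 and 6, TNBS 4 and 6, and IBC 4. The log2 differences of Gpr84 did not pass: 3.83 ± 1.27 for TNBS against vector (edgeR adjusted p = 0.182), -1.03 ± 1.09 for IBC against TNBS (0.929) and 2.81 ± 1.25 for IBC against vector (0.550). Without 1 library they ran from 3.12 to 4.89, from -1.30 to -0.309 and from 2.54 to 3.87. Akt1 was at 214 ± 25.8, 269 ± 60.6 and 218 ± 7.23 CPM in vector, TNBS and IBC, and its difference did not pass in any comparison (edgeR adjusted p = 0.238, 0.925 and 0.982 for TNBS against vector, IBC against TNBS and IBC against vector). Foxo3, a transcription factor that AKT inactivates, was at 74.7 ± 9.34, 48.7 ± 16.6 and 77.6 ± 13.3 CPM. It was lower in 6 of 6 TNBS libraries than the vector median (-0.62 ± 0.20, edgeR adjusted p = 0.172) and higher in 6 of 6 IBC libraries than the TNBS median (0.67 ± 0.20, edgeR adjusted p = 0.925). Foxo3 is not named in the title and was taken for its small p within the list in both comparisons. Both share the TNBS libraries with opposite sign, so a fall and a return can arise from that choice. Adjusted over the list alone and over all genes, 0 of the 30 GPR84 and PI3K-AKT genes passed in any comparison. These are transcript levels, and the activity of GPR84, PI3K or AKT was not measured. Neither this count nor the level of Foxo3 therefore speaks for or against a change in that activity.

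As a list, these GPR84 and PI3K-AKT genes differed by -0.12 (log2) between TNBS and vector, 0.17 between IBC and TNBS and 0.05 between IBC and vector, where the median was -0.06 (camera adjusted p = 0.131, 0.0871 and 0.776). For IBC against TNBS the list was called upward without TNBS 1 (0.20), TNBS 4 (0.18), TNBS 6 (0.21), IBC 2 (0.21) or IBC 5 (0.24). With all libraries it had adjusted p = 0.879 with an estimated correlation and an adjusted p of 0.910 with fry. Its differences were 0.28 in the 12 libraries high in Hoxb13 and -0.04 in the other 6. For IBC against vector these were 0.18 and -0.22, and for TNBS against vector -0.09 and -0.18. Il1b, Il6 and Tnf, cytokines of acute inflammation, did not pass over all genes either. Il1b was at 2.18 ± 1.35 CPM in vector, 11.3 ± 9.18 in TNBS and 13.5 ± 12.3 in IBC, and Tnf at 0.811 ± 0.547, 3.46 ± 2.38 and 2.25 ± 1.04 (SD, n = 6 each).

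**Figure D3:**
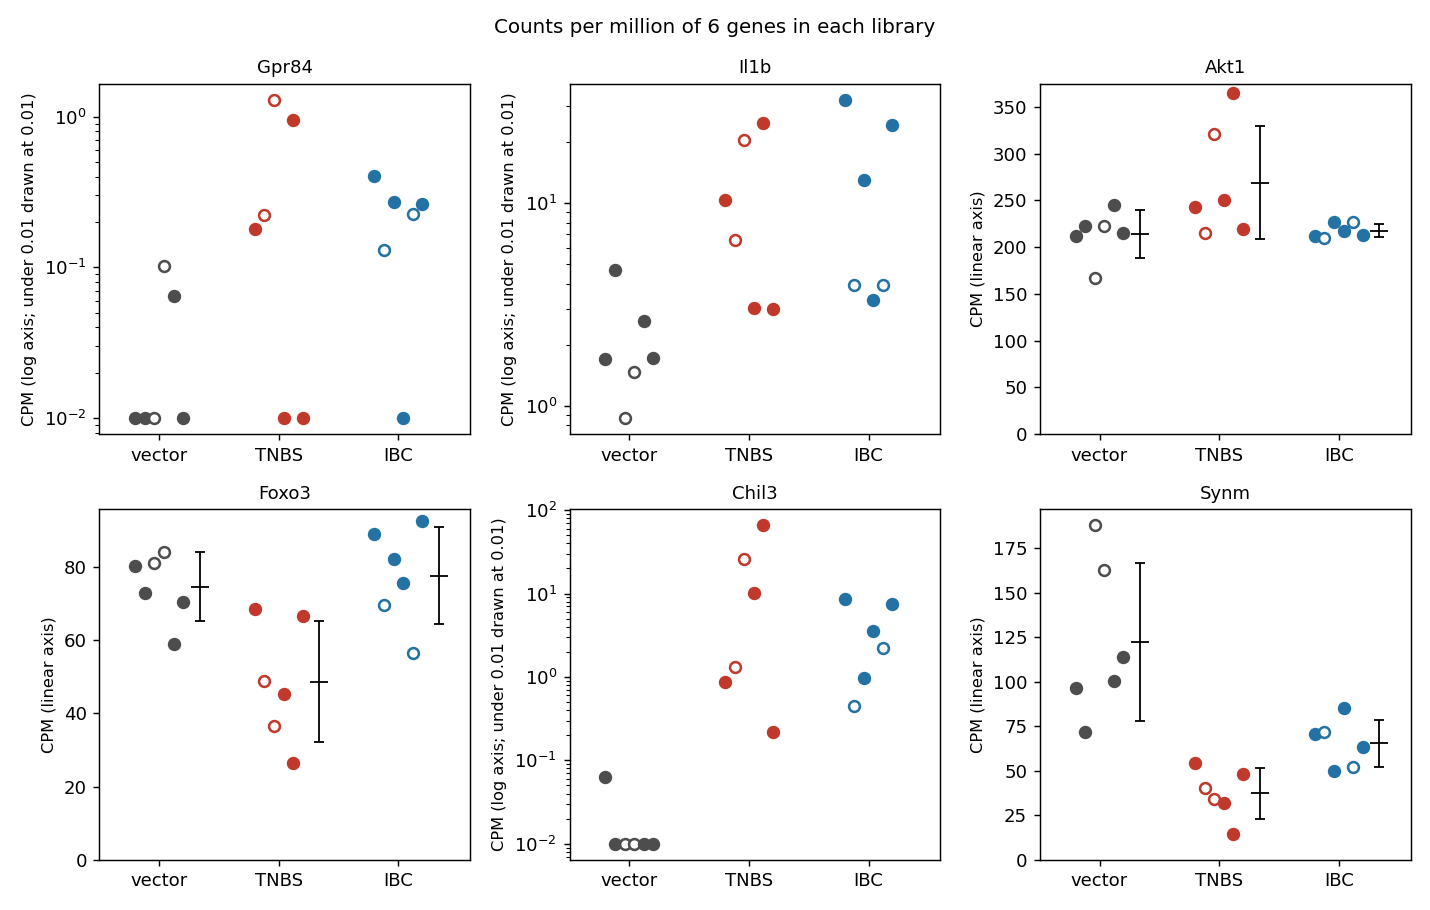
CPM per library by group for Gpr84, Il1b and Chil3 on a log axis, with values under 0.01 drawn at 0.01, and for Akt1, Foxo3 and Synm on a linear axis with the mean ± SD of n = 6. Synm fell from 122 to 37.2 CPM between vector and TNBS and was at 65.3 CPM in IBC.

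The comparison of IBC with TNBS asks what isobavachalcone changes beside the colitis model. With all 18 libraries neither the neutrophil nor the cytokine list was called by camera, and their scores differed by -0.15 (95% interval -1.98 to 1.61) and -0.19 (-1.41 to 1.04). With library weights neutrophil markers were called higher (0.742, adjusted p = 0.0482, in a range of 7.3e-12 to 0.928 over the alternatives). S100a8, the other calprotectin subunit, was at 15.8 ± 32.1 CPM in TNBS and 2.93 ± 3.33 in IBC (SD, n = 6 each). TNBS 5 alone had 80.9 CPM, 4 of 6 IBC libraries were higher than the TNBS median, and the log2 difference went from -2.43 to 0.10 without TNBS 5. Ccl2 was at 8.38 ± 7.29 and 3.73 ± 1.84 CPM. Synm was at 37.2 ± 14.1 and 65.3 ± 13.2 CPM, higher in 6 of 6 IBC libraries than the TNBS median (0.81 ± 0.27, edgeR adjusted p = 0.925). Ccl2 and Synm were also picked from TNBS against vector, which shares these TNBS libraries, so a move back can arise from that choice. Alox15, a lipoxygenase of eosinophils and macrophages, was at 1.17 ± 0.601 and 4.38 ± 2.33 CPM, higher in 5 of 6 (edgeR adjusted p = 0.925). Bcl3, a regulator of NF-kB, was at 65.3 ± 19.6 and 40.5 ± 10.1 CPM, lower in 6 of 6 (edgeR adjusted p = 0.925). The exact permutation p was 0.866 for the neutrophil score and 0.723 for the cytokine score, and their intervals leave room for differences of more than 1 log2 unit either way.

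With edgeR 0 genes passed between IBC and TNBS, with a smallest adjusted p of 0.925. At an unadjusted p under 0.05 there were 820 genes, 356 higher and 464 lower. Uniform p-values would give 1043, and other splits of the same libraries gave a median of 860 and up to 5823. Groups did not overlap for 31 genes (0.149%, against 0.216% expected for a random split, without a computed spread). The 820 became 2322 without IBC 5, 1694 without TNBS 6, 462 without IBC 1 and 486 without IBC 6. DESeq2 called 2 genes and limma on log2 FPKM called 0, and without IBC 4 edgeR called 1. The neutrophil difference turned positive without TNBS 5 (0.37) or IBC 2 (0.23), and cytokines were called lower without IBC 1 (-0.43). In the 12 libraries high in Hoxb13 and the other 6 the neutrophil difference was 0.49 and -1.43, and that of the cytokines 0.36 and -1.30, so their direction did not hold within the sets. In a fit of the 6 alone camera called both lists lower (-1.77 and -1.24), with 2 libraries per group, and neither was called there with an estimated correlation (adjusted p = 0.755 for each with an estimated correlation).

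Camera at the preset correlation called 4 of 31 lists between IBC and TNBS. Adipocyte markers were higher by 1.65 (log2, with a median of 0.38 over the members), smooth muscle markers by 0.39 and eosinophil markers by 0.81, and mitochondrially encoded mRNAs were lower by 0.36. Of their members 9 of 10, 11 of 12 and 5 of 5 were higher and 11 of 13 lower. Adjusted over the list alone 1 eosinophil gene and 0 genes of the other lists passed, against 0 over all genes. Each of the 4 lists had adjusted p = 0.879 with an estimated correlation, fry called 0, and the exact permutation p after adjustment was 0.403 for adipocyte, 0.201 for smooth muscle, 0.0839 for eosinophil and 0.229 for mitochondrial genes. In the 12 libraries high in Hoxb13 and the other 6 the differences were 2.68 and -0.42 for adipocyte, 0.47 and 0.25 for smooth muscle, 1.15 and 0.15 for eosinophil and -0.51 and -0.06 for mitochondrial genes. The eosinophil call was lost without TNBS 1 (0.77), TNBS 2 (0.76), TNBS 6 (0.83), IBC 3 (0.74) or IBC 5 (0.85), and that of smooth muscle without TNBS 6 (0.34) or IBC 5 (0.38). The number of lists called was 7 without TNBS 1 or TNBS 3, 8 without TNBS 4 or TNBS 5 and 9 without IBC 2. Mean and median differed in sign for the interferon (0.30 and -0.19), B and plasma cell (0.19 and -0.02), goblet cell (0.15 and -0.17), squamous epithelium (0.38 and -0.06) and enteric neuron lists (0.07 and -0.01), none of them called.

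Whether IBC moves genes against the direction of TNBS was read across genes, which are not independent replicates. Across 20855 genes the fold changes of IBC against TNBS and of TNBS against vector had a Pearson correlation of -0.525. Unchanged groups that share the TNBS libraries gave -0.493 ± 0.196 (SD of 100 simulations), so the value lies within what shared libraries give. With separate TNBS libraries in each contrast the median was -0.0376 (-0.249 to 0.236), and 11 of 20 assignments were negative. No gene was called by edgeR in both contrasts, in opposite directions or in the same. At an unadjusted edgeR p under 0.05, 371 genes moved in opposite directions and 3 in the same. The simulations gave a mean of 252 and a highest value of 2830 in opposite directions. They were tested with limma on log2 CPM rather than edgeR, so these counts are only roughly comparable.

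The comparison of IBC with vector asks how far IBC libraries lie from controls. Neutrophil markers and cytokines rose here too, by 2.52 (95% interval 1.24 to 3.78) and 2.07 (1.18 to 3.00) in log2, and both scores were higher in all 6 IBC libraries than in any vector library. Cxcl2, which attracts neutrophils, went from 0.0132 ± 0.0322 to 2.57 ± 2.82 CPM (SD, n = 6 each). Ccr2, the chemokine receptor of inflammatory monocytes, went from 3.37 ± 1.14 to 20.1 ± 12.95 CPM, and Arg1, an arginase of macrophages, from 0.819 ± 0.195 to 21.1 ± 19.9 CPM. In IBC 2 and IBC 5, both low in Hoxb13, Ccr2 was at 3.83 and 5.36 CPM and Arg1 at 2.99 and 1.93 CPM. The other IBC libraries had 22.3 to 35.3 CPM of Ccr2 and 8.74 to 45.5 CPM of Arg1. Red blood cell markers fell by 2.00 (95% interval -3.00 to -1.01), with Alas2, an enzyme of heme synthesis in red cells, at 2.41 ± 0.825 and 0.788 ± 0.419 CPM. Adjusted over the list alone 15 of 18 neutrophil genes, 15 of 19 cytokine genes and 12 of 20 monocyte and macrophage genes rose and 6 of 6 red blood cell genes fell, against 0 over all genes. The scores of neutrophils, cytokines and red blood cells each had an exact permutation p of 0.00216 and an adjusted p of 0.0403. Camera gave adjusted p = 0.0700 for neutrophil, adjusted p = 0.0590 for cytokine, adjusted p = 0.0615 for red blood cell and adjusted p = 0.103 for monocyte and macrophage genes with an estimated correlation. In the 12 libraries high in Hoxb13 and the other 6 the differences were 3.09 and 1.37 for neutrophils, 2.30 and 1.59 for cytokines, -2.47 and -1.06 for red blood cells and 1.26 and 0.60 for monocytes and macrophages.

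Camera at the preset correlation called 16 of 31 lists between IBC and vector, 13 up and 3 down, and fry called 6. Beyond those above, cell cycle genes were higher by 0.64 (log2), with 14 of 20 rising over the list alone, extracellular matrix genes by 1.05 (9 of 20), mast cell markers by 1.44 (3 of 8), eosinophil markers by 1.09 (2 of 5) and squamous epithelium by 1.13 (2 of 8). Mmp13, a collagenase, went from 1.79 ± 0.626 to 12.6 ± 10.6 CPM, and Hmox1, heme oxygenase, from 7.46 ± 3.48 to 31.6 ± 14.0 CPM (SD, n = 6 each). Antimicrobial genes (1.16), T cell markers (0.46), endothelial markers (0.28) and the NF-kB list (0.15) were called with 0 members passing over the list alone, and NRF2 and AhR targets (0.30) with 1 of 13. Smooth muscle markers were lower by 0.56 (1 of 12 fell over the list alone) and mitochondrially encoded mRNAs by 0.59 (4 of 13), beside the 17.98% of mitochondrial counts in vector 3. Without 1 library the smooth muscle difference ran from -0.689 to -0.350 and the mitochondrial one from -0.704 to -0.281. None of these genes passed over all genes tested. These 12 calls were lost at the estimated correlation, with adjusted p = 0.0873 for cell cycle, mast cell and eosinophil, adjusted p = 0.241 for extracellular matrix and smooth muscle, adjusted p = 0.103 for squamous epithelium and adjusted p = 0.0983 for antimicrobial lists with an estimated correlation. For the T cell, endothelial, NF-kB, NRF2 and mitochondrial lists it gave adjusted p = 0.503, adjusted p = 0.566, adjusted p = 0.298, adjusted p = 0.276 and adjusted p = 0.264.

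In the 12 libraries high in Hoxb13 and the other 6 the differences turned sign for extracellular matrix (1.78 and -0.41) and endothelial markers (0.66 and -0.50). In a fit of the 6 alone camera called both lists lower, extracellular matrix by 0.414 (adjusted p = 0.00773, in a range of 2.6e-22 to 0.650 over the alternatives) and endothelial markers by 0.505 (adjusted p = 0.0445, in a range of 3.5e-06 to 0.666). There they had adjusted p = 0.650 and adjusted p = 0.666 with an estimated correlation. That fit has 2 libraries per group, and its controls are vector 4 and vector 3, whose endothelial score was 0.71, against -0.48 to -0.10 in the other vector libraries. They were 0.42 and 1.06 for cell cycle, 1.53 and 1.24 for mast cell, 1.08 and 1.12 for eosinophil, 1.24 and 0.92 for squamous, 1.27 and 0.94 for antimicrobial and 0.42 and 0.52 for T cell lists. They were 0.22 and 0.03 for the NF-kB list, 0.28 and 0.33 for NRF2 and AhR targets, -0.32 and -1.03 for smooth muscle and -0.37 and -1.03 for mitochondrial genes. The NF-kB call was lost without vector 1 (0.13), IBC 1 (0.12) or IBC 6 (0.14), and that of NRF2 and AhR targets without vector 6 (0.27), IBC 2 (0.28) or IBC 5 (0.23). The T cell call was lost without vector 1 (0.25) or IBC 6 (0.33), and the endothelial call without vector 1 (0.21), vector 4 (0.20), IBC 1 (0.15) or IBC 6 (0.23). Mean and median differed in sign for the inflammasome (0.16 and -0.03), B and plasma cell (0.19 and -0.08) and crypt stem cell lists (0.12 and -0.03), none of them called.

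With edgeR 0 genes passed between IBC and vector, with a smallest adjusted p of 0.125. At an unadjusted p under 0.05 there were 1778 genes, 1021 higher and 757 lower. Uniform p-values would give 1043, and other splits of the same libraries gave a median of 488 and up to 2433. Groups did not overlap for 225 genes (1.08%, against 0.216% expected for a random split, without a computed spread). DESeq2 called 186 genes (133 up and 53 down), limma on log2 FPKM called 0 and limma with library weights called 610. Without IBC 2 edgeR called 5 genes, among them Ccr2 (2.79, adjusted p = 0.0213, in a range of 4.4e-05 to 0.373 over its alternatives). The 2 groups alone gave 8 genes, the Hox score as a covariate gave 39, the 12 libraries high in Hoxb13 gave 30 and the other 6 gave 0.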

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

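The tests in this part were chosen after the results they bear on were seen, except the splits fitted with the Hox score, whose possible outcomes were written down before they were run. In groups of 6 libraries, the highest or lowest library was set against the others by Dixon's test for 96 measures in 3 groups, leaving out 3 groups with 5 or more libraries at the same value. Of the other 285 groups 25 stood out, where chance gives about 1 in 20, or 14.25. Some measures overlap, such as those of mitochondrial genes, so these are not counts of independent tests.

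Vector 3 stood out most often, in part through overlapping measures of mitochondrial genes. It held 17.98% mitochondrial counts (others 5.55% to 7.08%), and its 10 most abundant genes took 19.9% (others 7.69% to 10.6%). Its scores were 1.73 for mitochondrially encoded mRNAs and 0.71 for endothelial markers. In log2 CPM it had mt-Nd2 at 12.70, mt-Atp8 at 11.79, mt-Nd3 at 8.38, Pck1 at 8.30, Lipe at 6.03, Hmox1 at 3.85, Mmp13 at -0.70 and Mmp10 at -1.08. In the other vector libraries vector 6 had Timp1 at 1.92, S100a8 at -5.04 and a pancreatic acinar score of 8.49 (others -0.98 to 0.44). Among TNBS libraries, TNBS 3 had an interferon score of 2.21 and an NF-kB score of 0.47, and TNBS 5 had an enteroendocrine score of 0.78, mt-Atp8 at 11.80 and mt-Nd3 at 9.14. Outside these measures, TNBS 5 lay at -147.5 on the second principal component (18.6% of the variance), against -44.4 to 61.5 in the other libraries. It also had the lowest library weight (0.189). Among IBC libraries, IBC 5 had a total of 78.9 in units of 1e6 counts (others 64.0 to 66.2) and an antimicrobial score of 1.83. IBC 2 had 7.51% mitochondrial counts and a mitochondrial score of 0.26, and IBC 4 had an interferon score of -1.04.

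One pattern is the 6 libraries low in Hoxb13. A difference in library size is argued against: after thinning all libraries to the same total, the highest Hoxb13 count of the 6 was 1.11% of the lowest of the 12, although the 6 were deeper (mean totals of 71.8 against 63.0 in units of 1e6 counts, exact permutation p = 0.00129). Inflammation as the source stays open. At most 2 of the 6 were among the 6 highest or 6 lowest neutrophil scores, but that test could not decide. All vector scores lay below all others and each group holds 2 of the 6, so nearly all 6 could not gather at either end. Scores of antimicrobial and injured epithelium genes were high in TNBS 3 (2.54), IBC 5 (1.83), TNBS 2 (0.90), vector 4 (0.61) and IBC 2 (0.39). In the last of the 6, vector 3, the score was -0.26, and TNBS 5 of the other 12 had 1.00. Pieces from different positions along the colon may be the source, but this cannot be told apart here, because 63.0% of the other Hox genes (17 of 27) followed the order of their paralog groups. Of paralog groups 9 and below 13 of 20 followed it, and those that did not were all Hoxa genes. Of groups 10 and above 4 of 7 followed it, and Hoxc10, Hoxd10 and Hoxd11 did not. The design names no group that matches the 6, so no biological explanation beyond inflammation and position was tested.

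Another is that 0 genes were called between IBC and TNBS. Spread from the position along the colon that is alike in all groups is argued against as the whole cause, since edgeR with the Hox score in the fit called 0 as well. That fit cannot speak to a group difference that varies with position. Such a difference stays open, since the neutrophil and cytokine differences had opposite signs in the libraries high and low in Hoxb13. A single library is also argued against as the whole cause, since leaving out any of the 12 libraries gave at most 1 gene. That count cannot show a smaller influence of single libraries. The 820 genes at an unadjusted edgeR p under 0.05 became 2322 without IBC 5, 1694 without TNBS 6 and 462 without IBC 1. At this size the gene test recovered 82% of simulated 4-fold changes and 42% of 2-fold changes. Those counts were drawn gene by gene, so the shares may not hold for the libraries themselves. Between TNBS and vector, S100a9 did not pass at a log2 difference of 5.73 ± 1.29 (edgeR adjusted p = 0.0909). Large as well as small differences between IBC and TNBS therefore remain open. The biological explanation, a small effect of isobavachalcone, was not tested.

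The last is the rise from 4 to 323 genes between TNBS and vector without TNBS 6. A wrong label, with TNBS 6 a vector library, might be the source and cannot be told apart from a weak response: TNBS 6 lay above the highest vector library by 1.41 SD of the vector libraries in the neutrophil score and by 1.35 SD in the cytokine score, under the limit of 2 SDs. At single genes chosen after their values were seen it lay outside the vector range toward TNBS (Mcpt1 at 7.59 CPM, highest vector 0.990, Mcpt2 at 3.37, highest vector 0.357, and Hbb-bt at 9.09, lowest vector 17.4) or away from it (Timp1 at 1.37, lowest vector 2.00). At Opcml, Synm and Disp3 it lay outside that range toward TNBS too, but these genes were called with TNBS 6 in the group. Over all genes 3.06% to 4.99% lay more than 2 SDs outside 5 vector libraries in TNBS 6, against 1.89% to 18.5% for a vector library left out. A test added later took the 323 genes that best set 5 TNBS from 5 vector libraries, where TNBS 6 lay 11.7% to 21.9% of the way from vector to TNBS and vector libraries left out of the choice 7.45% to 30.3% (smallest gap -2.32 SD); by itself it would allow the wrong label, but only through vector 3, since the next vector library lay at 17.1% and TNBS 6 lay farther in 5 of 6 choices. A swap with a vector library stays open. Exchanging vector 6 and TNBS 6 gave 695 genes with DESeq2 (real split 574) but 53 with the Hox score (real split 170). Exchanging vector 5 and TNBS 6 gave 514 with DESeq2 and 0 with the Hox score, both below the real split. A weak response of TNBS 6 was not tested.

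Other splits of the same libraries into groups of 6 were fitted in the same way, with the real split included. For TNBS against vector, 1 of 100 splits, the real one itself, called as many as the real 4 genes (highest other 1). Chance is argued against for that count but not excluded. Leaving out 1 library gave 0 to 323 genes, and the split tests were not adjusted for their number. Chance stays open for the 3703 genes at an unadjusted p under 0.05 (5 of 100 splits, highest other 4368), the 10 lists (52 of 100, highest other 15) and the 574 genes of DESeq2 (3 of 40, highest other 712). For the 3703 genes, the splits with 4368 and 3928 are the real split with TNBS 6 exchanged for vector 6 and vector 5. That with 3893 had 6 of 6 libraries on its one side high in Hoxb13, and that with 3821 had 3 of 6. For the DESeq2 count the reading rests on 2 splits. That with 712 genes had 6 of 6 libraries on its one side high in Hoxb13, and that with 695 set vector 1 to 5 and TNBS 6 against the rest, which is the real split with vector 6 and TNBS 6 exchanged. With the Hox score, 1 of 60 splits, again the real one, reached the real 170 genes (highest other 53). Chance is argued against there but not excluded, and 9 of the 170 remained without TNBS 5. For IBC against vector chance is argued against, but not excluded, for the 39 genes with the Hox score (1 of 60 splits, the real one, highest other 0). It stays open for the 1778 unadjusted genes (7 of 100, highest other 2433) and the 16 lists (15 of 100, highest other 20). The 0 genes allow no such reading, since every split has at least 0 (100 of 100, highest other 1). For IBC against TNBS chance cannot be excluded for the 820 unadjusted genes (55 of 100, highest other 5823) or the 4 lists (83 of 100, highest other 18), and the 0 genes again allow no reading (100 of 100, highest other 841). The split with 841 genes points to a structure of the samples beyond the groups; 5 of the 6 libraries on its one side were high in Hoxb13.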

How the results depend on the processing

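Chosen after the data were seen were the Hox score, the 12 libraries high in Hoxb13 or the other 6 alone (also with an estimated correlation), TNBS replicate 5 left out together with another choice, counts divided by 4, and the list counts and the reversal with 1 library left out. Of 180 values for the counts and the reversal, 122 kept their direction and side of the threshold or their size, 32 became weaker, 25 stronger and 1 moved. For named genes it was 2480 of 2715 (73 weaker, 118 stronger, 44 reversed), and for lists 759 of 959 (158 weaker, 18 stronger, 24 reversed). A named gene not called in the main fit counts as kept while it stays uncalled in the same direction. Only the 4 genes called between TNBS and vector could become weaker, and the 73 are all losses of their calls. Each of these 4 genes lost its call in most alternatives. The cause was not tested for any of the changes below. Between TNBS and vector, the 4 genes called became 0 in limma on log2 FPKM with a pseudocount of 1, 0.1 or 0.01, without a filter, with the stricter filter, with the 2 compared groups alone, with the 12 libraries, with the other 6 and with counts divided by 4. They became 1 with the replicate block, 7 with quantile normalization, 9 with library weights, 574 with DESeq2 (271 without TNBS 5) and 170 with the Hox score (10 without TNBS 5). Leaving out 1 library gave 0 to 323. Between IBC and TNBS, 0 became 2 with DESeq2, and leaving out 1 library gave 0 to 1. Between IBC and vector, 0 became 610 with library weights, 8 with the 2 groups alone, 186 with DESeq2, 39 with the Hox score and 30 with the 12 libraries, and leaving out 1 library gave 0 to 5. Of the gene lists, the 10 between TNBS and vector became 0 at the estimated correlation, and 8 to 12 without 1 library. The 4 between IBC and TNBS became 0 at the estimated correlation and with fry, 9 with library weights, 8 with the Hox score (9 without TNBS 5), 11 in the 12 libraries and 12 in the other 6, and 3 to 9 without 1 library. The 16 between IBC and vector became 0 at the estimated correlation and 6 with fry, and 14 to 21 without 1 library. The replicate block, with 7 of 18 same-numbered pairs above 0.1, gave 1, 0 and 0 genes and 9, 5 and 16 lists for TNBS against vector, IBC against TNBS and IBC against vector, and changed no other call among these counts. The correlation of TNBS with IBC changes was -0.0376 at the median with no TNBS library used in both contrasts, against -0.525, and -0.659 to -0.427 without 1 TNBS library. Results whose direction turned, with their log2 differences, were these. For IBC vs TNBS, Akt2 was at 0.0298, 0.0338 and 0.0343 with limma at a pseudocount of 1, 0.1 and 0.01, 0.0375 in the 12 libraries, and -0.155 to 0.0191 without 1 library. Pik3r5 was at 0.0662, 0.162 and 0.190 with limma at the same pseudocounts, 0.0129 without a filter, 0.00449 with the stricter filter, 0.00175 with quantile normalization, 0.201 with library weights, 0.0682 with the replicate block, 0.0877 in the 12 and -0.195 to 0.374 without 1 library. Il6 was at 0.484 with library weights, 0.267 with the replicate block, 0.366 in the 12 and -1.18 to 0.321 without 1 library. S100a8 was at 0.483 with library weights, 0.337 with the Hox score without TNBS 5 and -3.23 to 0.0957 without 1 library, and Gpr84 at 0.755 with library weights and 0.0515 with the Hox score without TNBS 5. Il1b was at -1.78 in the 6 low in Hoxb13 and -0.224 to 0.649 without 1 library. In the same 6, Pik3cg was at -0.0647, Csf1r at -0.0962 and mt-Nd3 at 0.150. For IBC vs vector, Akt1 was at -0.0217 with library weights, -0.0161 in the 12 and -0.0233 to 0.0658 without 1 library, and in the 6 Pik3cg was at -0.0513 and Mmp10 at -0.322. For TNBS vs vector, Pik3cg was at 0.0155 with the Hox score without TNBS 5 and 0.0134 in the 6, and Pik3cd at -0.0368 to 0.364 without 1 library. With an estimated correlation 0 lists were called in the 12 or the 6 in any comparison, with the same differences. Values in the 12 or the 6 come here from fits of the set alone, so they differ from those of scores scaled over all 18 libraries. Among lists the direction is that of camera, which can differ from the sign of the mean difference printed here. For IBC vs TNBS the 6 gave -0.0435 for GPR84 and PI3K-AKT components and -0.423 for adipocyte markers. Inflammatory cytokines and chemokines gave 0.133 with library weights and 0.486 in the 12, and neutrophil markers 0.742 with library weights (called higher there), 0.360 with the Hox score without TNBS 5, 0.512 in the 12 and -0.478 to 0.371 without 1 library. For IBC vs vector, GPR84 and PI3K-AKT components gave 0.140 with library weights, 0.208 in the 12 and -0.00362 to 0.113 without 1 library, and the 6 gave -0.505 for endothelial markers and -0.414 for extracellular matrix and remodelling, both called lower there, and extracellular matrix and remodelling was at 0.151 for TNBS vs vector. DESeq2 size factors and quantile normalization put the median of all genes at most 0.0198 from 0, and limma on log2(FPKM + 1), which changes more than the scaling, at most 0.0714. Depth limits what can be said of genes with few counts, such as Gpr84, Chil3 in vector and Disp3 in TNBS.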

Other observations

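The tests of this part were all chosen after the data were seen, except the test of handling, whose possible outcomes were written down before it was run. With the Hox score as a covariate, edgeR called 170 genes between TNBS and vector, 87 up and 83 down. Among them Myom1, a protein of the sarcomere, fell by 1.498 ± 0.194 (log2, SE), Myh11 by 1.64 ± 0.29, Mylk, the myosin light chain kinase, by 1.20 ± 0.21 and Smtn, smoothelin, by 1.03 ± 0.18. Myot, another protein of the sarcomere, rose by 4.86 ± 0.99. Clec4d, a lectin receptor of myeloid cells, rose by 4.38 ± 0.71 and Ccl2 by 3.08 ± 0.52. DESeq2 called 146 of the 170 genes in the same direction, and 9 of the 170 remained without TNBS 5. Between IBC and vector, 39 genes were called with the Hox score, 31 up and 8 down, and DESeq2 called 28 of them in the same direction. Among the 39, Ccr2 rose by 2.44 ± 0.31, the mannose receptor Mrc1 by 1.33 ± 0.22, Trem2 by 2.43 ± 0.43, Clec10a by 2.92 ± 0.54 and Csf3r, the receptor of a granulocyte growth factor, by 2.50 ± 0.48. All genes named here were chosen after their values were seen, and no theme among the called genes was tested.

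Among 330 KEGG pathways, camera at the preset correlation called 70 between TNBS and vector, 71 between IBC and TNBS and 45 between IBC and vector. Ribosome genes had a median difference of 0.59 (log2) between TNBS and vector and of -0.48 between IBC and TNBS, and oxidative phosphorylation genes of -0.26 between IBC and TNBS. The same TNBS libraries enter both contrasts with opposite sign. No pathway was called with fry or at the estimated correlation (smallest adjusted p = 0.775, adjusted p = 0.731 and adjusted p = 0.684 with an estimated correlation).

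Heat shock transcripts (10 genes, among them Hspa1a, Hspb1 and Dnajb1) were lower in IBC libraries. Their mean score was 0.15 ± 0.38 in vector, 0.34 ± 0.59 in TNBS and -0.49 ± 0.42 in IBC (SD, n = 6 each). IBC differed from TNBS by -0.83 (95% interval -1.51 to -0.18, exact permutation p = 0.0173, adjusted p = 0.0779 over 6 tests) and from vector by -0.64 (exact permutation p = 0.0260, adjusted p = 0.0779), so neither passed after adjustment. Handling of the tissue before lysis may move such transcripts and was tested by their relation to 10 immediate-early genes, such as Fos and Egr1. Across the 18 libraries with group means removed, Pearson's r was 0.268 (permutation p = 0.281) and Spearman's rho 0.271 (permutation p = 0.276), and r was 0.338 without TNBS 1 and vector 4, the libraries farthest from the median heat shock score. The relation does not decide for or against handling, which therefore cannot be told apart from a difference between groups.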
